A study of Mus musculus with 4 samples.

How the data were processed

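MED1 ChIP-seq was performed on RAW 264.7 cells that were untreated (2 libraries) or stimulated with LPS for 2 h (2 libraries). Per the labels' protocols, cells were fixed with DSG and then formaldehyde, chromatin was sonicated, MED1 was precipitated with an antibody, and the libraries were sequenced as single reads. Bowtie, SAMtools and MACS2 2.2.6 and the mm10 build are named in the submitters' processing notes. The settings of the peak calling, the use of a control library and whether libraries were pooled are not given in the sources used here. The deposited list gives the chromosome, start and end of 53764 intervals; the score that the authors deposited is 0 in every line and holds no measurement, and names and strands are dots. The list was deposited for the whole series, with 0 columns of other samples. Which libraries its intervals came from is not stated. No counts are given, so depth is unknown and no precision per library could be computed.

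The planned comparison of untreated with stimulated cells needs intervals assigned to a condition and was not made. The planned motif analysis needs a genome sequence and was not run. Gene positions came from the RefSeq annotation of GRCm38.p6, the assembly that mm10 names, with 21887 protein-coding genes on chromosomes 1 to 19, X and Y. Strand, exons and assembly gaps were not used here, so the planned distance from a transcription start was replaced by the distance from either gene end, exons and introns were pooled as inside a gene, and random placement ran from the first to the last annotated gene of each chromosome. Coordinates are 1-based.

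The plan took the deposited intervals as peaks. Because 31192 of them began exactly where the preceding one ended, abutting intervals were joined into regions, and the unjoined intervals were kept as an alternative. The 4 mitochondrial intervals were left out of all comparisons with genes. A region counted as near a gene when its midpoint lay within 50 kb of either end, and as at a gene end when its midpoint lay within 1 kb. Genomic classes were compared with 1000 random placements (two-sided permutation test by random placement, smallest possible p 0.0020). The 13 gene lists (333 members, 331 found in the annotation), the tests of regions near their genes, at gene ends and per gene, the first group of alternatives below and the rule for named genes were fixed before the data were examined. Shares of list genes were compared with all other protein-coding genes by two-sided Fisher's exact tests. Median numbers of regions per gene were compared with 10000 random lists drawn within deciles of local gene density (two-sided permutation test, smallest possible p 0.00020). The tests of single-interval regions and of the largest clusters on these lists were added afterwards. Shares of single-interval regions were compared with 10000 random sets of genes that have a region, over list genes at least 100 kb apart. P-values were adjusted over lists by the Benjamini-Hochberg method, with a threshold of 0.05. Neighbouring genes can share a region and are not independent, so the list tests were repeated with list genes within 100 kb of an earlier one left out (spaced list genes). Regions at most 12.5 kb apart were stitched into clusters, ranked by covered length. Intervals of percentages are Wilson 95% intervals.

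The genes named by rule were up to 4 members per list with the most regions within 50 kb, up to 2 members without one, the gene nearest to each of the 15 largest clusters and the gene nearest to each of the 10 widest regions. Some genes that this rule selects are not reported here. Other genes were chosen after their values were seen. The first group of alternatives was regions at or above the median width, merging within 500 bp, windows of 10 and 100 kb, a gene-end window of 2.5 kb, any overlap instead of the midpoint, a background of genes with a region at an end, no density matching, stitching within 5 kb, clusters without gene-end regions, and ranking by number of regions. Alternatives added after the data were examined were unjoined intervals, regions of 1 interval left out, matching on gene length, spaced list genes, distance from the gene body, and all alternatives of the added comparisons. A change of direction was counted as a change of the result only where a value passed the threshold.

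The list tests were tested on simulated data with random regions at the real gene positions. Lists given added regions were called in 20 of 20 runs by each of 3 tests, and unchanged lists in 0, 0 and 1 of 20 runs at an unadjusted threshold of 0.05. Simulated regions were placed uniformly, lists were random genes, and several regions were added per gene. The concentration of real regions at gene ends and neighbouring list genes that share regions were not simulated. Error rates and power for the real lists can therefore differ. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.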

Results

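Chromatin occupancy of MED1, a subunit of the Mediator complex that links transcription factors to RNA polymerase II, was profiled by ChIP-seq in RAW 264.7 cells, a mouse macrophage-like line. Cells were untreated (2 libraries) or stimulated for 2 h with lipopolysaccharide (LPS), a bacterial envelope component sensed by Toll-like receptor 4 (2 libraries). The sample labels give an LPS dose of 10 ng/mL and the treatment protocol gives 100 ng/mL, so the dose is uncertain. The values analysed are the positions of a list of intervals on mm10, deposited for the series of 4 libraries. The libraries that contributed to it are not named. No interval carries a name, a height or a significance, so none could be assigned to untreated or to stimulated cells, and the comparison of these conditions was not made. Read depth is unknown. The tests below compare genes and positions within this list and do not measure the spread between libraries.

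The deposited MED1 calls formed 22570 separate regions on chromosomes 1 to 19, X and Y, covering 59.7 Mb. The use of a control and the peak-calling settings are not given. Background calls among these regions could therefore not be told apart from MED1 occupancy. The median width of the regions was 1948 bp (quartiles 1302 and 3012 bp), and the widest reached 55273 bp. The autosomes carried between 71.6 and 130 regions per 100 protein-coding genes, the X chromosome carried 46.8 and the Y chromosome 1.95. The regions were obtained by joining 53760 deposited intervals wherever one began exactly where another ended. Most regions contained 3 abutting intervals (13627 regions, 60.4%) or a single interval (7957 regions, 35.3%), and 862 contained 5 or more. Single-interval regions had a median width of 1346 bp, against 2336 bp for the others.

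**Figure D1:**
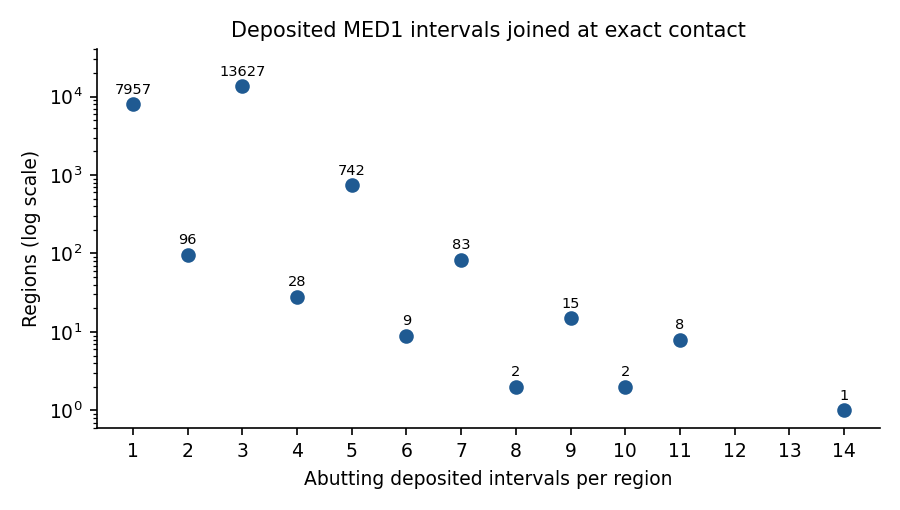
Number of MED1 regions on chromosomes 1 to 19, X and Y (log scale) by the number of abutting deposited intervals in the region, with each count printed above its point. Regions of 1 interval number 7957 and regions of 3 intervals 13627, while regions with an even number total 138.

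MED1 regions were concentrated at the ends of protein-coding genes. The midpoints of 7216 regions (32.0%) lay within 1 kb of a gene end, 10.1 times the 3.18% (central 95% 2.94 to 3.41) found when the same regions were placed at random on their own chromosomes (two-sided permutation test by random placement, p = 0.0020, the smallest that 1000 placements can give). Regions outside genes made up 28.8%, against 57.9% at random (permutation p = 0.0020). The remaining 39.3% lay inside genes, against 38.9% at random (permutation p = 0.254). Gene strand was not used here, so transcription start and end were not told apart; among genes longer than 10 kb, 5686 had a region midpoint at 1 end and 193 at both. Regions of several intervals had their midpoint at a gene end in 40.0% of cases and single-interval regions in 17.3% (odds ratio 0.313, two-sided Fisher's exact test, p = 3.54e-284). The share inside genes depended on the definition. It lay below random with a gene-end window of 2.5 kb (32.6%, ratio 0.889) and by any overlap (32.4%, ratio 0.877), and above random among regions at or above the median width (41.1%, ratio 1.05) and for unjoined intervals (41.0%, ratio 1.05, permutation p = 0.0020 each).

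Genes of the primary LPS response carried MED1 regions more often and in larger number than other genes. All 40 genes on this list had a region midpoint within 50 kb of a gene end, compared with 70.2% of other protein-coding genes. Their median was 5.5 regions per gene, against 2 (central 95% 1 to 3) for random lists matched on local gene density. The housekeeping list reached the same share and median (24 of 24 genes, 5.5 regions), so neither is particular to LPS response genes. Icam1, a leukocyte adhesion molecule (chromosome 9, 21015940 to 21028814), had 10 regions within 50 kb, 3 of them overlapping the gene. Ier3 and Fos, an AP-1 subunit, had 9 each and Marcksl1 had 8. Tnf, which encodes tumour necrosis factor (chromosome 17, 35199367 to 35202007), had 7 and lay entirely within a region of 33.3 kb (35192470 to 35225785) that also overlapped Ltb, Lta and Nfkbil1. The share of genes differed by a two-sided Fisher's exact test (Benjamini-Hochberg adjusted over 13 lists, p = 2.1e-05) and the median by a permutation test (adjusted p = 0.0013). When only genes with a region at an end were compared and regions at gene ends were not counted, none of the 12 testable lists passed the threshold. The primary (94.4%, adjusted p = 0.348) and lineage lists (100%, adjusted p = 0.334) still lay above the 74.7% of other such genes (Fisher's exact tests). Only 18 primary and 14 lineage genes remained, and 1 or 2 genes of the B cell, hepatocyte, neutrophil and muscle lists. With so few genes, the comparison does not show that the differences disappear. The neuronal list, with 0 genes with a midpoint at an end, could not be tested.

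The secondary and interferon response list had a region within 50 kb in 33 of 34 genes (97.1%, adjusted p = 0.00065, Fisher's exact test). Stat2, a transducer of type I interferon signals (chromosome 10, 128270498 to 128292853), had 11 regions, and Acod1, the itaconate-producing enzyme, had 9. The chemokine genes Cxcl10 and Cxcl9, whose 50 kb windows overlap, had 8 each. Il12b, encoding the p40 subunit of interleukin 12, was the exception, with the closest region midpoint 56.3 kb away. The median of 4 regions per gene did not pass the threshold against density-matched lists (2, central 95% 1 to 3.5, adjusted p = 0.0884, permutation test), and passed it with a window of 10 kb (adjusted p = 0.0173) or 100 kb (adjusted p = 0.0182) and among regions at or above the median width (adjusted p = 0.00087). It did not pass for unjoined intervals (adjusted p = 0.237), spaced list genes (adjusted p = 0.216), matching on gene length (adjusted p = 0.178) or no density matching (adjusted p = 0.0988, permutation tests). With single-interval regions left out it did not pass either (2 against 1.5).

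Macrophage lineage genes had a region within 50 kb in 33 of 35 cases (94.3%, adjusted p = 0.0016, Fisher's exact test) and a median of 6 regions per gene, against 1 (central 95% 0 to 3) for density-matched lists (adjusted p = 0.0013, permutation test). Lyz2, encoding lysozyme (chromosome 10, 117277541 to 117282272), had 12 regions, 4 of them overlapping the gene. The transcription factor gene Runx1 had 10, and Irf8 and the Fc receptor gene Fcgr1 had 9 each. The transcription factor gene Maf and the scavenger receptor gene Marco had none, with the closest midpoints 280 and 181 kb away.

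The study's title concerns 2-ketoacid dehydrogenases bound to Mediator and the acetyl-CoA they supply for histone acetylation. A list of 2-ketoacid dehydrogenase and acetyl-CoA genes was tested, called dehydrogenase genes here for short. Besides subunits of these enzymes, it holds their regulatory kinases and phosphatases. It also holds Acly, Acss2, Slc25a1 and Cs, which are not dehydrogenase genes. On this list, 18 of 21 genes had a region midpoint within 1 kb of an end (85.7%, against 36.8% of other genes, adjusted p = 3.7e-05, Fisher's exact test). Such a share is not particular to this list. Among gene families grouped later by symbol, proteasome (42 of 49, 85.7%) and NADH dehydrogenase subunit genes (34 of 40, 85%) reached it, and ribosomal protein genes had 67.4%. Citrate synthase, Cs (chromosome 10, 128337727 to 128362482), had 10 regions within 50 kb, Bckdha had 9, and Ogdh and Bckdk had 7 each. Counts within 50 kb include regions at neighbouring genes and can repeat a region within or between lists. The windows of Cs and Stat2 overlap, as do those of Hdac1 and Marcksl1. Those of Hdac1 and Lck, of Bckdk and Kat8, and of Med16, Prtn3 and Elane overlap too. Pdk4, encoding a kinase that inhibits pyruvate dehydrogenase, had none, with the closest midpoint 157 kb away. Mediator genes had a midpoint at an end in 29 of 33 cases (87.9%, adjusted p = 2.3e-08, Fisher's exact test), with 12 regions within 50 kb at Cdk19, 9 at Med16, 8 each at Med24 and Ccnc, and none at Med12l. Genes of histone acetylation did in 18 of 26 cases (69.2%, adjusted p = 0.0026, Fisher's exact test), with 11 regions at Sirt7, 10 at Hdac1, and 8 each at Kat8 and Sirt2. Housekeeping genes did in 17 of 24 cases (70.8%, adjusted p = 0.0026, Fisher's exact test), with 11 regions at Rps18, 10 each at Eef1a1 and Polr2a, and 8 at Rplp0. Within 50 kb these lists also exceeded other genes, with 20 of 21 dehydrogenase genes (adjusted p = 0.0133), 32 of 33 Mediator genes (adjusted p = 0.00065), all 26 histone acetylation genes (adjusted p = 0.00065) and all 24 housekeeping genes (adjusted p = 0.0011, Fisher's exact tests). The 50 kb window includes the gene ends, so these shares are not a separate result. Counting only regions away from gene ends, among genes with a region at an end, none passed the threshold of Fisher's exact test. The shares were then 77.8% (dehydrogenase), 79.3% (Mediator), 77.8% (histone acetylation) and 82.4% (housekeeping), against about 74.8% of other such genes. The dehydrogenase call was lost with a window of 100 kb (adjusted p = 0.0931, Fisher's exact test). Median regions per gene passed the permutation test for housekeeping genes (5.5 against 3, adjusted p = 0.0043), though not within 10 kb (adjusted p = 0.0936), and not for the dehydrogenase (4 against 2, adjusted p = 0.329), Mediator (4 against 2, adjusted p = 0.226) or histone acetylation lists (3 against 2.5, adjusted p = 0.999). Within 10 kb, the Mediator (2 against 1, adjusted p = 0.0240) and histone acetylation lists (2 against 1, adjusted p = 0.0442, permutation tests) passed. Among regions at or above the median width, the gene-end calls of the Mediator list (21.2%, adjusted p = 0.895) and the histone acetylation list (19.2%, adjusted p = 1.0) were lost by Fisher's exact test. The histone acetylation call was also lost with single-interval regions left out (46.2%, adjusted p = 0.174, Fisher's exact test).

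By the same midpoint criterion, the primary LPS response list (18 of 40, 45.0%, adjusted p = 0.352), the secondary list (17 of 34, 50.0%, adjusted p = 0.193) and the lineage list (14 of 35, 40.0%, adjusted p = 0.727) did not differ from other genes by Fisher's exact test. When any overlap of a region with the gene-end window was counted, a criterion added after the data were examined, they did, with 38 of 40 (95%, adjusted p = 3.2e-10), 29 of 34 (85.3%, adjusted p = 6.0e-06) and 30 of 35 genes (85.7%, adjusted p = 4.1e-06), against 45.5% of other genes (Fisher's exact tests). These lists also passed the threshold with a window of 2.5 kb and among regions at or above the median width. The secondary list also passed with spaced list genes (59.3%, adjusted p = 0.0374, Fisher's exact test). With single-interval regions left out none of them passed, and the secondary list lay below other genes (20.6% against 30.8%, adjusted p = 0.312, Fisher's exact test).

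Marker genes of several other cell types had few MED1 regions at their ends. A region midpoint lay within 1 kb of an end in 0 of 24 neuronal genes (adjusted p = 8.7e-05), 1 of 20 hepatocyte genes (adjusted p = 0.0041), 1 of 18 B cell genes (adjusted p = 0.010) and 2 of 20 skeletal muscle genes (adjusted p = 0.017), against about 36.9% of other genes (Fisher's exact tests). T cell genes (4 of 20, adjusted p = 0.193) and neutrophil and granulocyte genes (2 of 16, adjusted p = 0.095) did not pass the threshold of Fisher's exact test. With single-interval regions left out, both passed it (5%, adjusted p = 0.0207, and 0%, adjusted p = 0.0103, Fisher's exact tests). The T cell list also passed among regions at or above the median width (0%, adjusted p = 0.0309) and the neutrophil list with spaced list genes (7.14%, adjusted p = 0.0374, Fisher's exact tests). With a window of 2.5 kb or by any overlap, the neutrophil list was close to other genes (43.8% each, against 45.3 and 45.5%, adjusted p = 1.0, Fisher's exact tests). Within 50 kb, only the neuronal list was lower (9 of 24, 37.5%, adjusted p = 0.0020), joined within 10 kb by the hepatocyte and muscle lists (30% each, adjusted p = 0.0319, Fisher's exact tests). The T cell (16 of 20, adjusted p = 0.55), B cell (14 of 18, adjusted p = 0.627), neutrophil (15 of 16, adjusted p = 0.0745), hepatocyte (13 of 20, adjusted p = 0.627) and muscle lists (11 of 20, adjusted p = 0.189) did not differ by Fisher's exact test, and none of these lists passed the test of median regions per gene matched on gene density. Matched on gene length, the neuronal list did (0 against 2, adjusted p = 0.0403, permutation test). Genes without a region within 50 kb of an end included Gabrb2, Alb and Apob, Acta1 and Myf5, Cd2 and Cd8a, Cd22, Ly6g, and Bank1, whose body was overlapped by 1 region. The B cell call at gene ends was lost with a window of 2.5 kb (27.8%, adjusted p = 0.189) and among regions at or above the median width (5.56%, adjusted p = 0.270, Fisher's exact tests). The muscle call was lost with spaced list genes (adjusted p = 0.0855, Fisher's exact test).

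Some markers of other lineages lay among many regions. Cd4 had 15 within 50 kb, although none overlapped the gene, and Lck had 12. Fcrla, Prtn3, Elane, Mylpf and Ryr1 had 9 each, and Grin1 and Hnf4a had 8 each. Other members with the most regions were Cd79b (7), Fcer2a, Fpr1 and Tnni2 (6 each), Cd3g, Blnk, Csf3r, Syn2, Apoa2 and Actn3 (5 each), Cd5, Slc17a7 and Syn1 (4 each) and Apoa1 (3). These counts include regions at neighbouring genes.

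**Figure D2:**
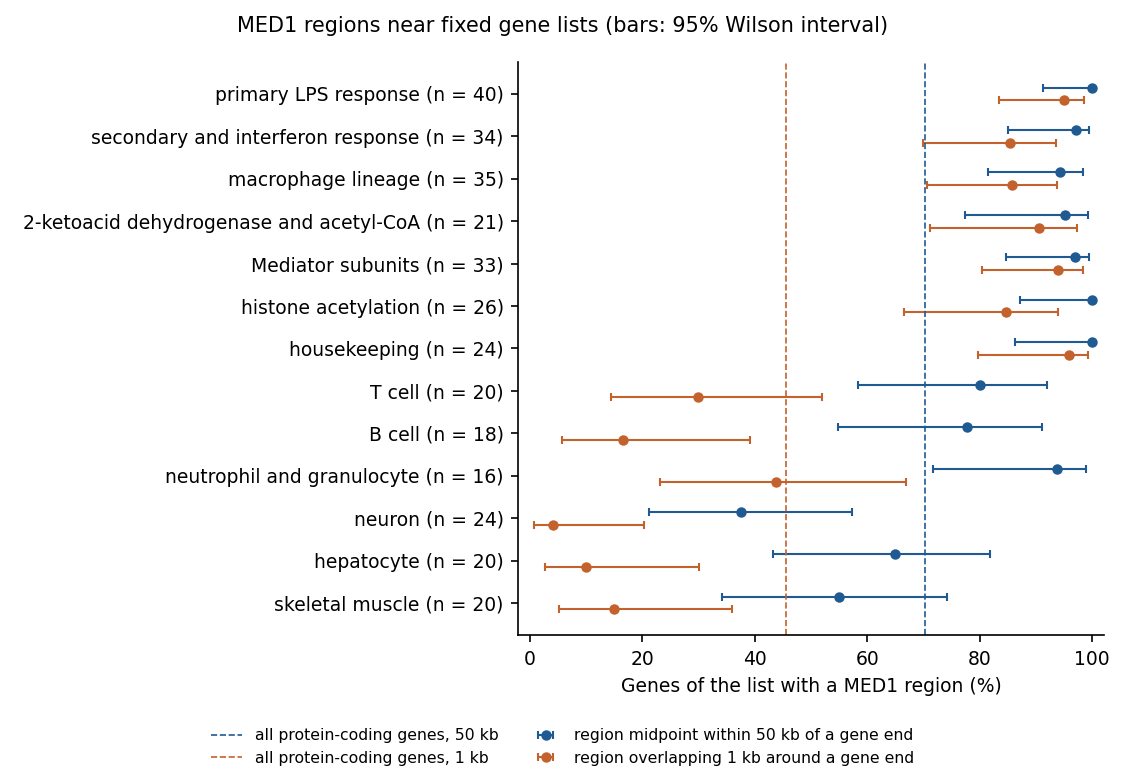
Percentage of the genes of each list (x axis) with a MED1 region midpoint within 50 kb of a gene end (blue) or with a region overlapping 1 kb around a gene end (orange), with Wilson 95% intervals; dashed lines mark all protein-coding genes. The neuronal list lies lowest on both measures, at 37.5% and 4.17%, and the primary LPS response list lies at 100% and 95%. The overlap criterion for lists was added after the data were examined. By the midpoint criterion fixed before, the primary list had 45.0% at an end, against 36.8% of other genes (adjusted p = 0.352, Fisher's exact test).

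Stitched regions formed 13554 clusters, and the largest 5% (677 clusters) held 28.1% of the covered length. The largest cluster, with 10 regions covering 112.0 kb, lay over Ahnak (chromosome 19, 8919539 to 9083825). It was followed by a cluster of 13 regions covering 102.8 kb at the chemokine genes Ccl5, Ccl9, Ccl6, Ccl3 and Ccl4 (chromosome 11, 83521992 to 83669532; nearest gene to its middle Ccl6), and by clusters at Ptprj, a receptor phosphatase gene (90.6 kb), nearest Tmco5 (86.4 kb; 66.5 kb from the middle of the cluster) and at Malt1, a paracaspase gene of NF-kB signalling (83.3 kb). A pair of clusters had Lpp as nearest gene (79.6 and 75.2 kb), and others lay near the ferritin gene Fth1 (78.7 kb), at Tnf with Nfkbil1 as nearest gene (71.5 kb; chromosome 17, 35162952 to 35263890) and at Mapkapk2, a p38-activated kinase gene (70.2 kb). Xirp1, Tnfrsf1b, Plekho2, Dock10 and Frmd8 were nearest to the remaining clusters among the largest 15. The Xirp1 cluster also overlapped Cx3cr1, and the Frmd8 cluster overlapped the long non-coding RNAs Malat1 and Neat1. Of the 14 nearest genes, 3 were shared when clusters were ranked by number of regions. The 10 widest single regions measured 33.3 to 55.3 kb, with Ptprj, Plekho2, Spdye4c, Slco4a1, Mcl1, Vmp1, Tex13c3, Ahnak (2 regions) and Lta as nearest genes. The region nearest Vmp1 overlapped Mir21a, the X-chromosomal region nearest Tex13c3 overlapped Mir221 and Mir222, and the region nearest Spdye4c overlapped the non-coding RNA Morrbid.

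The largest 5% of clusters overlapped 27 of the 40 primary LPS response genes (67.5%, against 5.34% of other genes, adjusted p = 4.7e-24), 19 of 35 macrophage lineage genes (54.3%, adjusted p = 1.0e-14), 12 of 34 secondary and interferon response genes (35.3%, adjusted p = 5.1e-07) and 7 of 24 housekeeping genes (29.2%, adjusted p = 0.00070, Fisher's exact tests). These tests were added after the data were examined, as were the genes named next. Primary genes in such clusters included Nfkbiz (52.0 kb covered), Socs3 (48.2 kb), Dusp1 (39.8 kb) and Nfkbia (27.6 kb), and lineage genes included Cd14 (59.2 kb), Lcp1 (52.3 kb), Spi1 (31.8 kb) and Csf1r (31.0 kb). Mediator genes (4 of 33, adjusted p = 0.268), histone acetylation genes (3 of 26, adjusted p = 0.361) and dehydrogenase genes (0 of 21, adjusted p = 0.815) did not differ from other genes, nor did T cell (0 of 20) and B cell genes (0 of 18, adjusted p = 0.815 each) or neutrophil (1 of 16, adjusted p = 0.815), neuronal (1 of 24), hepatocyte (1 of 20) and muscle genes (1 of 20, adjusted p = 1.0 each, Fisher's exact tests). With regions within 2.5 kb of a gene end left out, the housekeeping list fell to 0% (adjusted p = 1.0) and the secondary list to 8.82% (adjusted p = 0.0729, Fisher's exact tests). The primary list, at 30% (adjusted p = 1.1e-11), and the lineage list, at 28.6% (adjusted p = 8.0e-10), stayed past the threshold (Fisher's exact tests).

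Near secondary and interferon response genes, more regions consisted of a single interval than near random genes. Of 119 regions within 50 kb of 26 loci, 54 (45.4%) were single intervals, against 30.4% (central 95% 21.3 to 40.0) around random genes (permutation test, adjusted p = 0.0416). At Rsad2, an interferon-induced antiviral gene, 5 of 6 regions were single intervals, at the chemokine gene Ccl2 5 of 7, and at the co-stimulatory receptor gene Cd40 3 of 3, whereas Cxcl10 had 1 of 8 and Lcn2 0 of 4. The share was 27.9% near primary LPS response genes (adjusted p = 0.683), 29.8% near lineage genes (adjusted p = 0.897), 28.9% near dehydrogenase genes (adjusted p = 0.842), 26.2% near Mediator genes (adjusted p = 0.683), 34.2% near histone acetylation genes (adjusted p = 0.683) and 22.5% near housekeeping genes (adjusted p = 0.348, permutation tests). It was 49.1% near T cell genes (adjusted p = 0.0559) and 45.5% near neutrophil genes (adjusted p = 0.15), and near the B cell, neuronal, hepatocyte and muscle lists it ranged from 27.0 to 37.5% (adjusted p from 0.683 to 0.808, permutation tests). This comparison and its examples were chosen after the data were examined. The call was lost when any of 14 of the 26 loci was left out (shares of 43.4 to 45.2%, adjusted p up to 0.0715 without Rsad2, permutation tests). It was also lost within 100 kb (42.8%, adjusted p = 0.0624), and within 10 kb the T cell list passed too (57.9%, adjusted p = 0.0364, permutation tests).

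**Figure D3:**
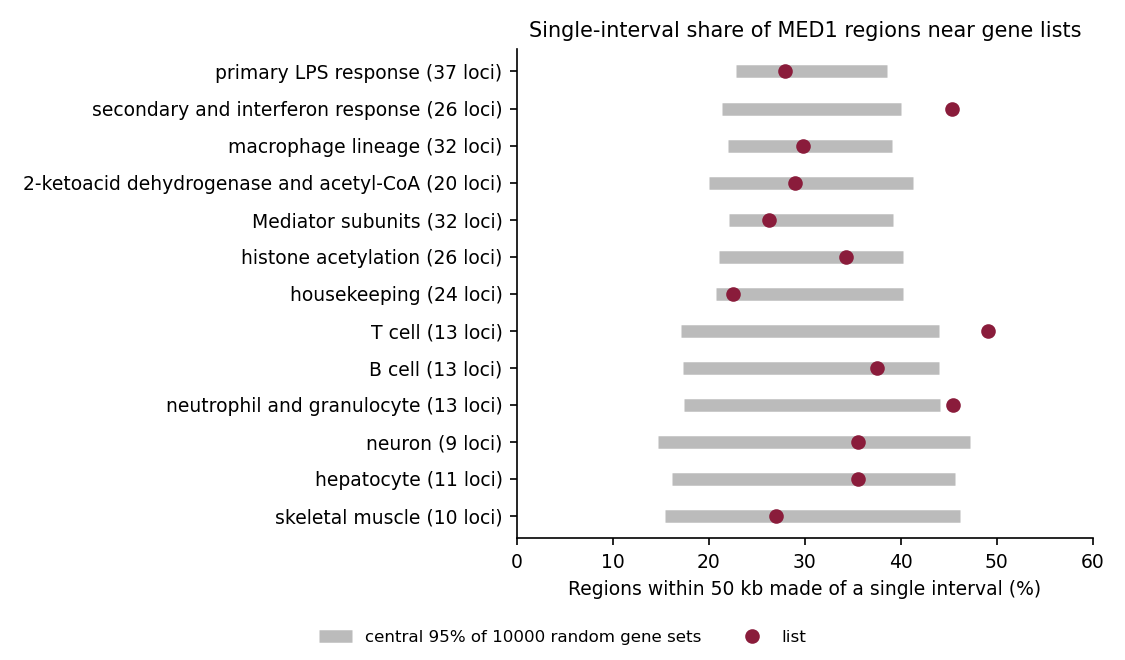
Percentage of MED1 regions within 50 kb of each list's loci that consist of a single interval (points, x axis), with the central 95% of 10000 random gene sets as grey bars. The secondary and interferon response list lies at 45.4%, above its random range of 21.3 to 40.0%. The T cell list (49.1%, range 17.1 to 44.0%) and the neutrophil list (45.5%, range 17.4 to 44.1%) also lie above theirs. Only the secondary list passed the threshold after adjustment.

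**Figure D4:**
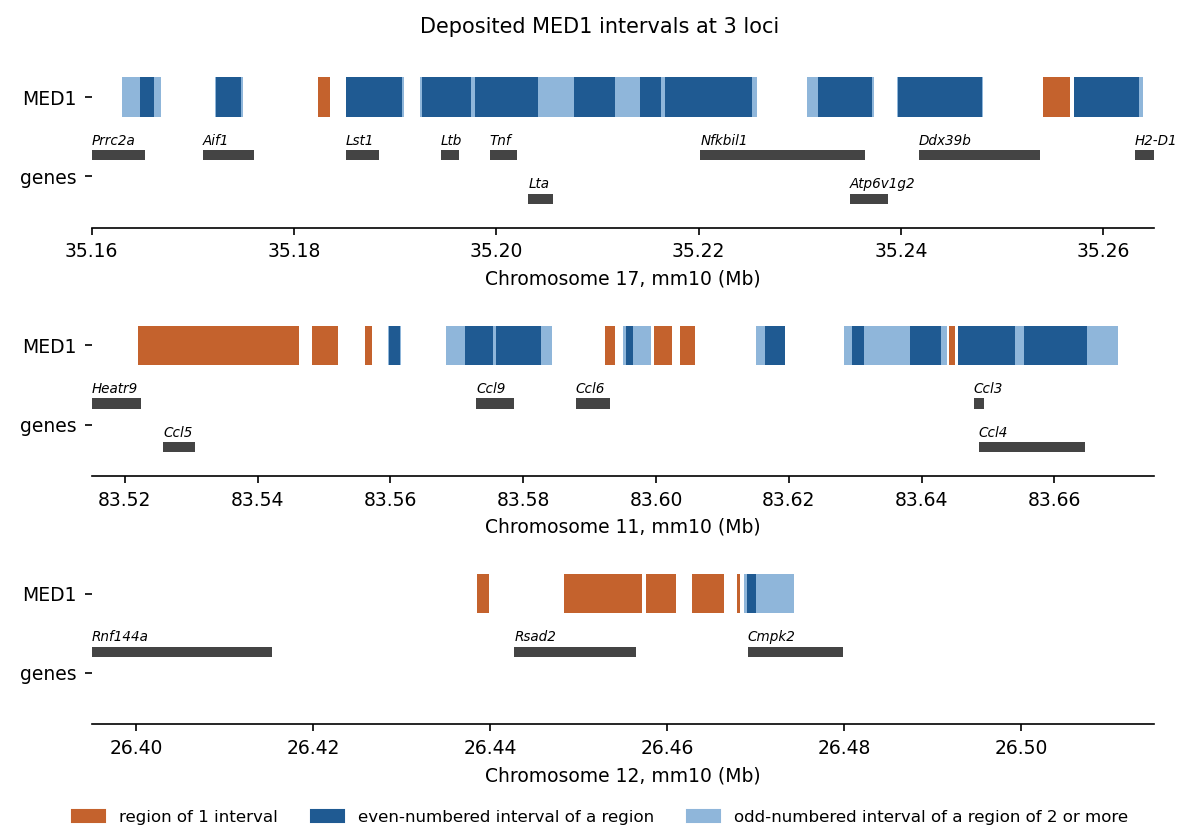
Deposited MED1 intervals and protein-coding genes (dark grey bars) at the Tnf, Ccl and Rsad2 loci; x axes give the mm10 position in Mb, orange marks regions of 1 interval, and dark and light blue mark even-numbered and odd-numbered intervals of larger regions. The region over Tnf holds 11 intervals, whereas 5 of the 6 regions at Rsad2 are single intervals.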

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

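The mitochondrial genome, which no comparison used, held 4 deposited intervals. They formed 2 regions covering 10250 bp, or 62.9% of the sequence up to the end of the last interval. No control library was used here to set a background for them, and no explanation was tested.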

How the results depend on the processing

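Alternatives to the comparisons of single-interval shares, of gene-end shares by list and of lists in the largest clusters were added after the data were examined, as were unjoined intervals and matching on gene length. No paired analysis was possible because the list holds no values per library, and for the same reason no library could be left out. The motif alternatives (no genome sequence) and those of untreated against LPS (no condition per interval) were not run. Of the values for single lists or genes, 306 kept their direction and side of the threshold. Another 42 changed direction, or moved to or from no direction, without a call before or after. Of the rest, 16 lost the call in the same direction, 2 lost it and changed direction, and 23 gained it. The cause was not tested for any change below, except where fewer regions or intervals remained by construction. There were 11288 regions at or above the median width, and 53760 unjoined intervals with a median of 687 bp. The share inside genes (39.3%) was 41.1% among wide regions and 41.0% for unjoined intervals, now above random, and fell below random to 32.6% with a 2.5 kb gene-end window and 32.4% by any overlap (permutation p = 0.0020 each). Lists with more genes near a region numbered 7. They numbered 0 when only genes with a region at an end were compared and regions at gene ends were not counted. That comparison left as few as 1 gene in a list. Lists with fewer numbered 1 (neuron), but 3 within 10 kb; the comparison of genes with a region at an end could not test it, since 0 neuronal genes have a midpoint there. Lists higher at gene ends rose from 4 to 7 with a 2.5 kb window and to 7 by any overlap, and the histone acetylation call was lost among wide regions (19.2%, p = 1.0, Fisher's exact test). Lists with more regions per gene rose from 3 to 5 within 10 kb, and lists with fewer from 0 to 1 when matched on gene length (neuron). Lists with a higher single-interval share numbered 1, but 2 within 10 kb and 0 within 100 kb. Leaving out gene-end regions gave 8754 clusters, 2 lists instead of 4 in the largest of them, and a housekeeping call lost at 0% (p = 1.0, Fisher's exact test). Of the 14 nearest genes of the largest clusters, 9 were shared with stitching within 5 kb, 8 without gene-end regions and 3 when ranked by number. Without counts, limits set by depth could not be assessed.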

Other observations

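The tests of interval structure and the comparisons of single-interval shares, gene families, gene length, wide single-interval regions and the X chromosome were chosen after the data were examined. Matching on gene density was planned, but its result had been seen when it was taken as a test of an explanation. Gene families grouped by symbol differed in coverage at gene ends, with 12 of 20 families past the threshold (Fisher's exact tests, Benjamini-Hochberg adjusted over 20 families). These tests count each gene as independent and were not repeated with spaced genes. Where neighbouring family members share a region or lack one together, their p-values are too small. A region overlapped the gene-end window in 74 of 78 mitochondrial ribosomal protein genes (94.9%, adjusted p = 4.2e-20), 46 of 49 proteasome genes (93.9%, adjusted p = 1.7e-12), 38 of 40 NADH dehydrogenase subunit genes (95%, adjusted p = 5.4e-11), 81 of 86 ribosomal protein genes (94.2%, adjusted p = 2.3e-21), 9 of 9 interferon regulatory factor genes (adjusted p = 0.0015), 16 of 22 V-ATPase genes (adjusted p = 0.027) and 242 of 397 zinc finger genes (61.0%, adjusted p = 1.1e-09, Fisher's exact tests). It did so in 7 of 1110 olfactory receptor genes (adjusted p = 1.1e-285), 1 of 353 vomeronasal receptor genes (adjusted p = 3.1e-91), 1 of 70 defensin genes (adjusted p = 8.1e-17) and 0 of 53 keratin genes (adjusted p = 3.7e-14, Fisher's exact tests). Histone genes were higher by overlap (59 of 67, adjusted p = 1.2e-12) and lower by midpoint (13 of 67, adjusted p = 0.0061, Fisher's exact tests). Chemokine genes were lower by midpoint (6 of 37, adjusted p = 0.016), with 14 of 37 by overlap (adjusted p = 0.513, Fisher's exact tests). The Toll-like receptor (8 of 12), guanylate-binding protein (6 of 10), IFIT (3 of 6), OAS (7 of 11), Schlafen (6 of 8), cathepsin (10 of 23) and TRIM families (34 of 68) did not pass the threshold by overlap (adjusted p from 0.226 to 1.0, Fisher's exact tests).

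On the X chromosome, 45.8% of 452 regions were single intervals, against 35.0% on the autosomes (odds ratio 1.57, two-sided Fisher's exact test, p = 3.46e-06), where single chromosomes ranged from 31.6 to 38.1%; regions on X were also narrower, with a median of 1493.5 against 1957 bp.

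Genes of the secondary and interferon response list were overlapped by wide single-interval regions more often than other genes. Among the widest 5% of single-interval regions (399 regions, at least 3776 bp), one or more overlapped 11 of 34 genes of the list (32.4%, against 1.08% of other genes, adjusted p = 8.95e-13, Fisher's exact test): Ifnb1, Ccl5, Ifit1, Ifit2, Oasl2, Rsad2, Gbp2, Gbp5, Cd40, Ptges and Edn1. The widest of all, 24.3 kb, lay over Ccl5 (chromosome 11, 83521992 to 83546306), and the next ones over Cadm1 (21.7 kb) and over Mir155hg (20.4 kb). Some of the list genes named are neighbours. With spaced list genes, 8 of 27 secondary genes were overlapped (29.6%, against 1.09% of other genes, adjusted p = 5.6e-09, Fisher's exact test). The primary LPS response list had 7 of 40 genes (17.5%, adjusted p = 1.9e-06) and the lineage list 4 of 35 (11.4%, adjusted p = 0.0027, Fisher's exact tests). Regions as wide with several intervals overlapped 34 of 40 primary genes (85%), 23 of 35 lineage genes (65.7%) and 13 of 34 secondary genes (38.2%). Among genes overlapped by any region that wide, the primary (7 of 35, adjusted p = 0.253) and lineage lists (4 of 23, adjusted p = 0.803) did not pass the threshold (Fisher's exact tests). For the secondary list, wide regions of any kind are not a sufficient explanation, since among such genes it still had a single-interval one more often (11 of 22, 50.0% against 9.13%, p = 1.23e-06, Fisher's exact test). The Ccl5 and Rsad2 loci had been seen before this test. Without them and with loci at least 100 kb apart, 6 of 16 genes had such a region (37.5% against 9.31%, adjusted p = 0.0290, Fisher's exact test). That is not independent support. The list had already shown an excess of single-interval regions in the same data, and Cd40, an example named above, was kept.

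The number of intervals per region has a pattern that may come from 2 sets of calls cut at each other's edges. Division of single calls at summits is argued against by the odd number of intervals in 99.1% of regions with 2 or more. The first explanation stays open. The inner odd-numbered intervals of regions with 5 or more would then be gaps between calls of a set, and 0 of 985 were at or below 300 bp. This count does not decide the question, because the limit was chosen after the narrowest (301 bp) was seen. Even-numbered intervals of the same regions reached down to 6 bp, with 32 of 1833 at or below the limit. The data do not tell what the sets would be. No biological explanation of this pattern was tested.

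For the excess of single-interval regions near secondary and interferon response genes, narrow regions were tested and argued against: the share lay 18.8 points above that expected from the width and gene-end position of the same regions (permutation p = 0.00020, the smallest possible, adjusted p = 0.0026). The excess did not rest on a single locus alone: with each locus left out in turn the share stayed between 43.4 and 47.7%, and the highest unadjusted permutation p was 0.011 (without Rsad2). The call over 13 lists was less stable, since the adjusted p rose from 0.0416 to between 0.0546 and 0.0715 (permutation tests) without any of Rsad2, Ccl2, Cd40, Ccl5, Il10, Nos2, Gbp2, Il6, Zbp1, Edn1, Ifnb1, Isg15, Ptges or Usp18, and stayed under the threshold without any of the other 12 loci. LPS stimulation adding or removing calls near these genes might account for it, but cannot be told apart from other causes, because 0 intervals have a name that tells the condition. The excess was not past the threshold within 100 kb. T cell and neutrophil lists had shares as high (49.1 and 45.5%), so a high share is not particular to the secondary list. Their excess over the width and position expectation was smaller (11.8 points, adjusted p = 0.238, and 6.32 points, adjusted p = 0.673, permutation tests).

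For the larger number of regions at primary LPS response genes, local gene density and gene length were tested as explanations. Both are argued against, since the median of 5.5 lay above that of lists matched on gene density (permutation p = 0.00020, the smallest possible) and of lists matched on gene length (p = 0.00020). Housekeeping genes had the same median of 5.5, so the larger number is not particular to LPS response genes. Whether stimulation adds regions at primary LPS response genes stays open, since no interval is assigned to a condition.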
